A study of Mus musculus with 8 samples.

How the data were processed

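Airway epithelial cells had been sorted by flow cytometry from the lungs of C57BL/6 mice, per the labels' protocols. Total RNA was extracted with TRIzol, and strand-specific libraries were built with a low-input kit, per the labels' protocols. The 8 libraries fall into 4 groups of 2: wild type (STAT3-WT, here WT) or conditional knockout (STAT3-cKO, here cKO), each given house dust mite (HDM) or phosphate-buffered saline (PBS). The cell type in which the knockout was made, the HDM schedule and the sex of the mice are not given in the sources used here.

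The deposited table holds 25124 gene symbols and a signal value per gene and library, which is a read count after the authors' normalization. HOMER and DESeq2 are named as tools and mm10 as the genome build, per the submitters' processing notes. The aligner, the annotation release, the tool versions and whether strand was used in counting are not given in the sources used here. Without a statement on strand, reads of overlapping and antisense genes cannot be assigned with certainty, and genes with near-identical copies may share reads.

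Within each library every non-zero value was a whole multiple of 1 step, the value of 1 read, so that 100% of the values came out whole within a tolerance of 0.01 reads. Dividing by that step recovered the whole reads, 232556 to 593200 per library, a 2.55-fold range. These are shallow libraries. A gene at 0 reads in a library allows up to 3 reads, which is 1.96 to 4.88 normalized counts depending on the library. That floor and the exact Clopper-Pearson 95% intervals given for shares of reads cover counting error only, since reads without molecular identifiers are not independent molecules.

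Values were analysed as log2(value + 1). Genes with a mean of at least 10 normalized counts over the 8 libraries were tested, which kept 7512. Fold changes are therefore on the log2(value + 1) scale and understate the change of low genes. A model with 1 mean per group was fitted to all 8 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a trend), so that the groups share 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as passing. All tests were two-sided. Errors given after ± on log2 fold changes are standard errors from limma, and those on normalized counts are standard deviations over the 2 libraries of a group.

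The 7 comparisons were HDM against PBS in each genotype, cKO against WT in each treatment, the genotype by treatment interaction, and each factor averaged over the other. Gene lists were tested with camera from limma at its preset inter-gene correlation of 0.01. Of 33 lists, 24 had at least 5 measured members and were tested, with Benjamini-Hochberg adjustment over the lists within a comparison. Each list call was repeated with the correlation estimated from the data. The tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where stated. The edgeR and DESeq2 alternatives and 4 further lists were added after the data had been seen.

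The genes named in each comparison are the 8 largest rises and 8 largest falls among genes that passed with no overlap between the libraries of the groups (for the interaction, among genes that passed). Predicted, clone-named and small RNA genes were left out. Where fewer than 8 passed in a direction, the list was filled to 4 with the genes of smallest unadjusted p, which are stated not to have passed. Up to 4 members with the smallest p were added from each list that passed or held a gene that passed. Stat3, Socs3, Muc5ac, Clca1, Il33, Tslp, Scgb1a1, Sftpc, Foxj1, Epcam and Ptprc were followed throughout where measured.

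The alternatives were a pseudocount 5 times larger or smaller, no filter on low values or a minimum mean of 50, size factors recomputed by median of ratios, quantile normalization, variance models without a trend or with robust settings, library weights, a replicate block, each library left out in turn, and fits of only the groups compared. For the gene lists, fry from limma was run as well. The recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0.

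The gene test and the list test at the preset correlation were tried on simulated data for 1 comparison, and the other tests were not. Reads were drawn for the 7512 genes from the means and depths of the real libraries, for HDM against PBS in WT, with 50 genes changed at each of 4 fold sizes. limma recovered 4% of 2-fold, 40% of 4-fold, 70% of 8-fold and 78% of 16-fold changes, with 7 false calls among 103. The list test recovered 10 of 10 lists of 20 genes changed 2-fold and called 0 of 20 unchanged lists. The simulated genes were drawn independently of each other. The simulation therefore cannot show how often the preset correlation gives false calls where the members of a list are correlated.

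Gene positions were taken from the RefSeq annotation of GRCm38.p6, the assembly that mm10 names, by matching symbols. Of the 25124 symbols, 24693 matched. The table lists no mitochondrial genes, so that a mitochondrial share could not be computed. Results of 1 gene that passed are not reported here, though the counts of genes include it.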

Results

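The data are RNA-seq profiles of sorted mouse cells labelled airway epithelial cells, a name for cells that line the conducting airways. They come from WT mice and mice with a conditional knockout of STAT3, a transcription factor activated by cytokines such as IL-6, after HDM or PBS. HDM is an allergen that causes type 2 airway inflammation in mice. Sftpc, a surfactant gene of alveolar type 2 cells, had means of 2198 (WT HDM), 828 (cKO HDM), 1027 (WT PBS) and 1095 (cKO PBS) normalized counts. Alveolar transcripts were thus present in every group, and changes in them need not be changes within conducting airway cells. Each of the 4 groups had 2 libraries, with 593200 and 317735 reads in WT HDM, 510931 and 454248 in cKO HDM, 480163 and 411098 in WT PBS, and 232556 and 298311 in cKO PBS. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. Replicates correlated across genes at r = 0.56 in cKO PBS, 0.68 in WT HDM and 0.77 in cKO HDM and WT PBS. The first WT HDM library was closer to both cKO HDM libraries and both WT PBS libraries (0.69 to 0.71) than to its replicate. Each cKO PBS library was closer to both cKO HDM and both WT PBS libraries (0.61 to 0.69) than to its replicate. On the first principal component (30.8% of variance) the first cKO PBS library, the shallowest, stood at 93.7 and the second WT HDM library at -63.4, with the other 6 from -26.3 to 8.05. Their counts differed by 4.82 to 6.27 times the sampling noise (chi-square per degree of freedom), so no library was a copy of its replicate.

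Stat3, the targeted gene (chromosome 11, 100886806 to 100939594, mm10), was measured first. It stood at 145 ± 16.7 normalized counts in WT HDM, 84.6 ± 10.8 in cKO HDM, 58.4 ± 24.6 in WT PBS and 76.7 ± 28.0 in cKO PBS (SD, n = 2 each). The individual libraries held 134 and 157 in WT HDM, 76.9 and 92.2 in cKO HDM, 75.8 and 40.9 in WT PBS, and 56.9 and 96.5 in cKO PBS. Under HDM the log2 difference of cKO against WT was -0.78 ± 0.39 (limma unadjusted p = 0.065, adjusted p = 0.549), with a 95% interval of -1.61 to 0.055. Under PBS it was 0.41 ± 0.39 (limma adjusted p = 0.845), with a 95% interval of -0.43 to 1.24. Stat3 transcript was thus not detectably lower in the PBS libraries labelled cKO, and its difference under HDM did not pass. These are totals over all exons, and a deletion of some exons need not lower them. The genotype is therefore given below as labelled, and every direction between genotypes rests on the labels.

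**Figure D1:**
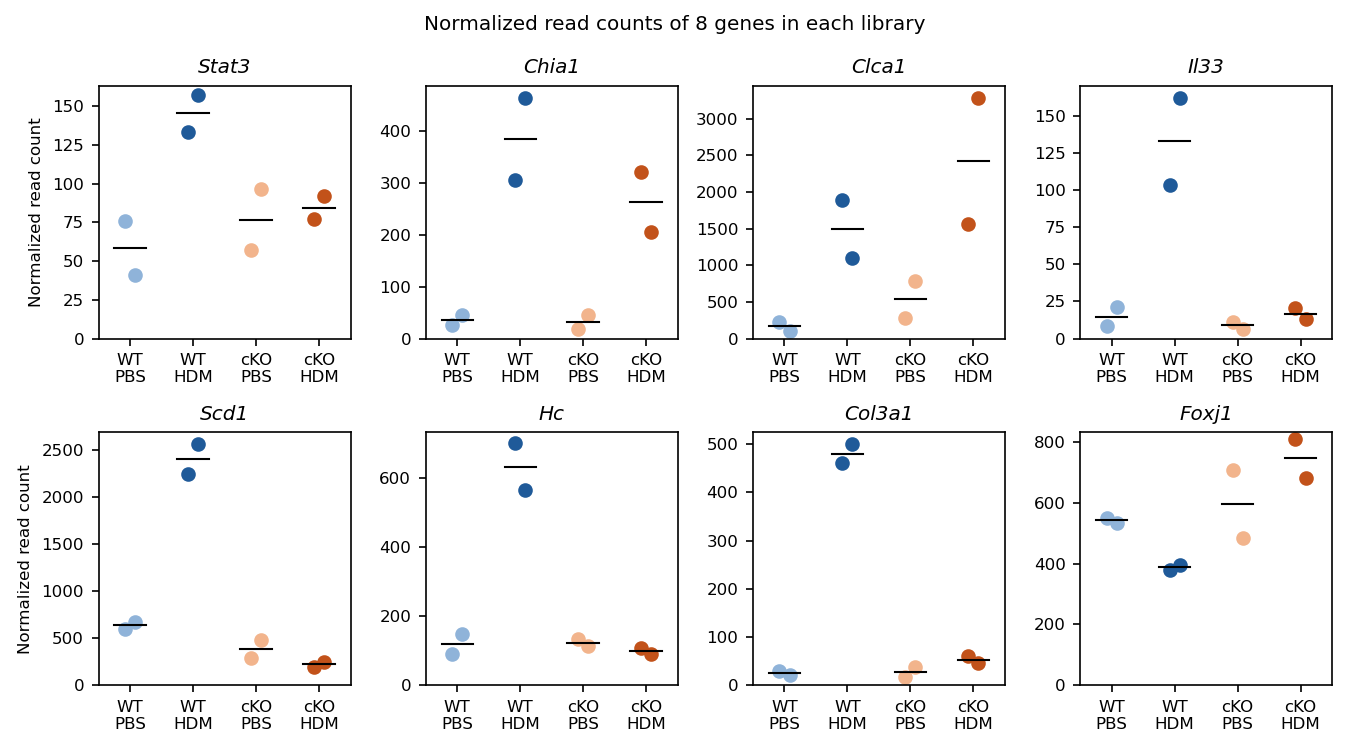
Normalized read counts (vertical axis, linear from 0) of 8 genes in each library, by group (horizontal axis), with points for the 2 libraries and a bar for their mean. Stat3 overlaps between the PBS groups, with 75.8 and 40.9 in WT and 56.9 and 96.5 in the libraries labelled cKO, while Scd1 stands at 2406 in WT HDM and 219 in cKO HDM.

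The first comparison asked how the sorted cells of WT mice responded to HDM. Secretory genes of the type 2 response rose: Chia1, an acidic chitinase, by 3.39 ± 0.44 log2 units, Clca1, a secreted protein of mucous cells, by 3.23 ± 0.46, and Retnla, a type 2 effector, by 3.13 ± 0.41. Clca1 went from 166 ± 90.9 to 1494 ± 552 normalized counts (SD, n = 2). Genes of the alveolar type 2 list rose as well, with Chil1 up 2.37 ± 0.23, Hc, complement C5, up 2.44 ± 0.30, and Scd1, a fatty acid desaturase, up 1.92 ± 0.25. The alarmin Il33, also a member of the alveolar type 2 list, rose by 3.19 ± 0.66, from 14.7 ± 8.84 to 133 ± 41.5 normalized counts. In all, 38 genes rose and 1 fell of 7512 tested (limma, adjusted p under 0.05), and edgeR called 56 and 3.

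Of the 18 measured genes of the IL-13 and mucous list, 6 rose over all genes tested, and 10 rose and 1 fell adjusted over the list alone (camera adjusted p = 4.4e-10, and adjusted p = 0.0227 with an estimated correlation). They included Slc26a4, an anion exchanger, at 6.11 ± 1.28, Chil3 at 5.48 ± 0.85 and Chil4 at 5.01 ± 0.86. Chil3 and Chil4 are close paralogs, and their reads may be split with error. Muc5ac, a gel-forming mucin, stood at 2.47 ± 0.96 and did not pass (limma adjusted p = 0.436). Of 23 alveolar type 2 genes, 10 rose, and 19 adjusted over the list alone (camera adjusted p = 4.6e-17, and adjusted p = 0.067 with an estimated correlation). Of 5 MHC class II genes 3 rose, Cd74, H2-Aa and H2-Eb1, by 2.81 ± 0.40, 3.01 ± 0.60 and 3.55 ± 0.71, and 4 adjusted over the list alone (adjusted p = 0.0772 with an estimated correlation). Macrophage and dendritic cell genes took 0.387% and 0.634% of reads in WT HDM, against 0.148% and 0.243% in WT PBS. Which cells gave the MHC class II transcripts therefore cannot be told here. H2-D1 was the 1 of 13 MHC class I genes that rose, by 1.32 ± 0.24, with 4 adjusted over the list alone (adjusted p = 0.067 with an estimated correlation). Genes of related copies in the MHC may share reads.

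Markers of other cell types were higher in the same 2 libraries. Endothelial genes had a median of 2.42, with all 15 measured members positive, 2 past the threshold (Calcrl 2.23 ± 0.46 and Vwf 2.11 ± 0.44) and 13 adjusted over the list alone (camera adjusted p = 2.3e-15, and adjusted p = 0.022 with an estimated correlation). Of 10 fibroblast and smooth muscle genes 3 rose, the collagens Col3a1 by 4.23 ± 0.43, Col1a2 by 4.51 ± 0.90 and Col1a1 by 3.57 ± 0.52, and 7 adjusted over the list alone (adjusted p = 0.0227 with an estimated correlation). The matrix genes Bgn and Sparc rose by 4.25 ± 0.87 and 4.42 ± 0.83, and Fn1, fibronectin, by 3.47 ± 0.52. Fn1 rose as much in the libraries labelled cKO (3.57 ± 0.52), where Sparc stood at 3.68 ± 0.83 (limma adjusted p = 0.19) and Bgn at -1.65 ± 0.87 (limma adjusted p = 0.662), so not all matrix genes were higher in WT HDM alone. The 22 endothelial genes listed took 0.349% (95% interval 0.335 to 0.365) and 0.373% (0.352 to 0.395) of reads in WT HDM, against 0.0889% (0.0807 to 0.0978) and 0.0800% (0.0716 to 0.0892) in WT PBS. Tslp, another alarmin, had 0 reads in every library. Ptprc, the pan-leukocyte marker, was too low to be tested, with 24.9 ± 17.7 normalized counts in WT HDM and 1.82 ± 2.57 in WT PBS. Epcam, the epithelial surface marker, stood at -0.17 ± 0.31 (limma adjusted p = 0.935).

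The 29 ciliated cell genes were lower as a list, with a median of -0.65 and 26 negative, 0 past the threshold and 10 adjusted over the list alone (camera adjusted p = 1.0e-06, and adjusted p = 0.0258 with an estimated correlation). Dnah5, an axonemal dynein, stood at -0.91 ± 0.24 (limma adjusted p = 0.128). The 24 STAT3 target genes had a median of 0.78, with 0 past the threshold with limma and 3 adjusted over the list alone (adjusted p = 0.067 with an estimated correlation). Among them Il4ra, an IL-4 and IL-13 receptor chain, stood at 2.90 ± 0.88 and Pim1, a kinase, at 3.66 ± 1.13, and neither passed with limma. Socs3, a feedback inhibitor of STAT3, stood at 1.84 ± 0.95 (limma adjusted p = 0.619), and Stat3 itself at 1.36 ± 0.39 (limma adjusted p = 0.189). Lists of macrophage and dendritic cell genes, the unfolded protein response, interferon and NF-kB responses also passed upward. With an estimated correlation their adjusted p were 0.067, 0.07, 0.381 and 0.142. Scgb1a1, the club cell secretoglobin, stood at -0.11 ± 0.24, Foxj1, the ciliated cell regulator, at -0.49 ± 0.23 and Sftpc, surfactant protein C, at 1.07 ± 0.28, none past the threshold. Without the second WT HDM library or the first WT PBS library, 3 genes passed in place of 39, and without the first WT HDM library 63 passed, of which 45 were lower. Counts were 14 without the second WT PBS library, 18 and 17 without the first and second cKO HDM library, and 108 and 110 without those of cKO PBS.

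The next comparison asked for the same response in mice labelled cKO. Chil4 rose by 7.04 ± 0.86 log2 units, from 1.90 ± 2.69 to 312 ± 173 normalized counts (SD, n = 2). The cKO PBS mean lies below the floor of 3 reads, 4.88 and 3.81 normalized counts in its libraries. The size of this rise therefore depends on the pseudocount. Chia1 rose by 3.14 ± 0.44, Fn1 by 3.57 ± 0.52, and Timp2, a metalloproteinase inhibitor, by 2.99 ± 0.47. These 4 genes rose and 0 fell (limma), with the same counts by edgeR, and 584 genes had an unadjusted p under 0.05. Retnla at 2.31 ± 0.41 (limma adjusted p = 0.0632) and Clca1 at 2.27 ± 0.46 (limma adjusted p = 0.13) were positive without passing. Of the IL-13 and mucous list 2 genes rose, and 6 adjusted over the list alone, with a median of 1.53 (camera adjusted p = 3.4e-04, but adjusted p = 0.291 with an estimated correlation). MHC class I genes had a median of 1.10, 0 past the threshold and 3 adjusted over the list alone (adjusted p = 0.582 with an estimated correlation). Club cell genes had a median of -0.71, 0 past the threshold, and 8 lower and 1 higher adjusted over the list alone (adjusted p = 0.708 with an estimated correlation). Cyp2f2, a club cell cytochrome, stood at -1.07 ± 0.21 and Scgb1a1 at -0.90 ± 0.24, and neither passed. Ribosomal protein genes had a median of -0.21 (adjusted p = 0.777 with an estimated correlation). The endothelial list had a median of 0.19 and the alveolar type 2 list one of -0.29, and neither passed. Il33 stood at 0.87 ± 0.66, Muc5ac at 1.31 ± 0.96 and Stat3 at 0.18 ± 0.39. Of the 38 genes that rose in WT, 29 were positive in the libraries labelled cKO, with a median of 0.76 against 2.41. The genes were selected by their rise in WT, which raises the WT median alone. A smaller median in cKO would arise from that selection even with equal responses. Across all genes the fold changes of both genotypes correlated at r = 0.08. All calls were lost without either WT HDM library or the first cKO HDM library, and without the first and second cKO PBS library 54 and 320 genes passed.

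**Figure D2:**
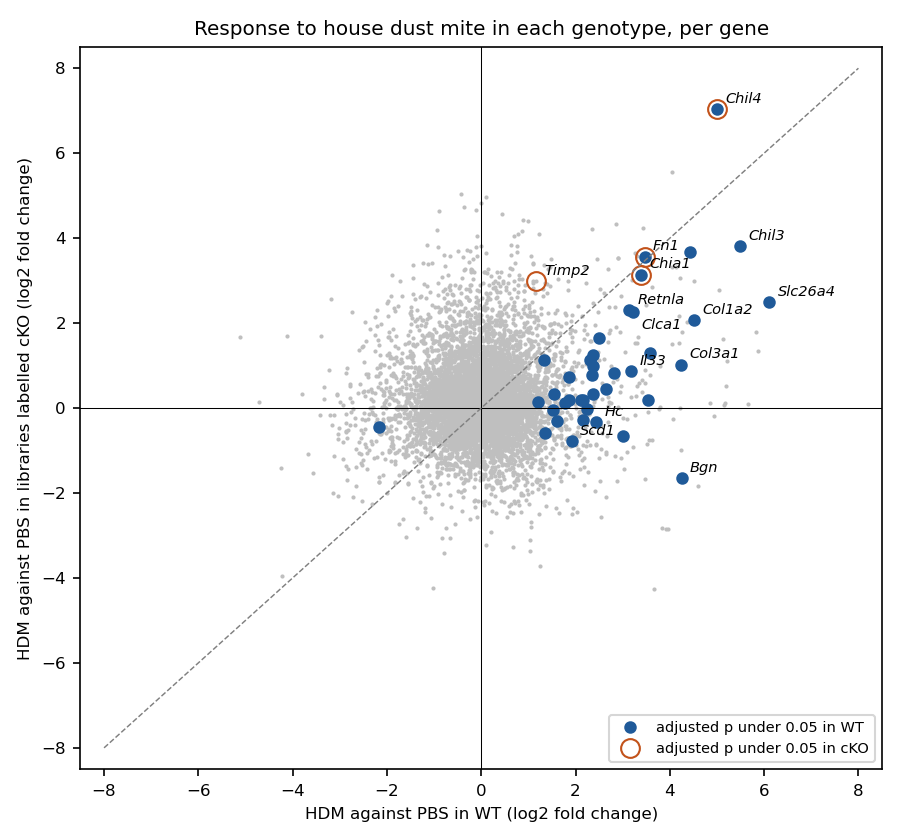
Log2 fold change of HDM against PBS in WT (horizontal axis) and in libraries labelled cKO (vertical axis) for each tested gene, with filled points for genes past the threshold in WT, open circles for those past it in cKO, and a dashed line of equal response. Chia1 lies near that line, at 3.39 and 3.14, while Scd1 and Hc lie far below it.

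The comparison of genotypes under HDM is the one named in the study's title. Alveolar type 2 genes were lower in the libraries labelled cKO: Scd1 fell by 3.46 ± 0.25 log2 units, from 2406 ± 231 normalized counts in WT to 219 ± 35.1 (SD, n = 2, limma adjusted p = 3.0e-06). Hc fell by 2.68 ± 0.30, Fasn, fatty acid synthase, by 2.16 ± 0.26, and Slc34a2, a phosphate transporter, by 2.15 ± 0.28. Pim1 had 0 reads in both cKO HDM libraries against 68.9 ± 35.7 normalized counts in WT, at least 29.5-fold lower against a floor of 3 reads per library. Tef, a clock-controlled transcription factor, rose by 2.30 ± 0.39, Fsd1l by 2.21 ± 0.42 and Dnah5 by 1.13 ± 0.24. In all 4 genes rose and 39 fell (limma), and edgeR called 5 and 49.

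Of the 23 alveolar type 2 genes 13 fell, and 21 adjusted over the list alone, with a median of -1.82 (camera adjusted p = 4.4e-20, and adjusted p = 0.0637 with an estimated correlation). Cxcl15, a lung chemokine, fell by 1.78 ± 0.24 and Sftpc by 1.34 ± 0.28. Of the alveolar type 1 genes Ager and Cav1 fell, at -1.69 ± 0.36 and -2.50 ± 0.49, and the list of 15 did not pass. Cav1 is also abundant in endothelium. The 29 ciliated genes were all positive, with a median of 0.92, 1 past the threshold and 16 adjusted over the list alone (adjusted p = 0.021 with an estimated correlation), and Foxj1 stood at 0.94 ± 0.23 (limma adjusted p = 0.0952). Of the 24 STAT3 target genes Pim1 alone fell, with 2 adjusted over the list alone and a median of -0.79 (adjusted p = 0.0812 with an estimated correlation). Pim1 was not lower in cKO without allergen: cKO against WT under PBS it stood at 1.89, and HDM against PBS in cKO at -4.27. Neither value passed. Under HDM, Lrg1, an acute-phase glycoprotein, stood at -4.33 ± 1.18 (cKO against WT) and did not pass. NF-kB response genes had a median of -1.40 with 0 past the threshold (adjusted p = 0.0812 with an estimated correlation), and Icam1 stood at -1.46 ± 0.56. MHC class II genes had a median of -2.25, with Cd74 and H2-Aa past the threshold at -2.25 ± 0.40 and -3.01 ± 0.60, and 4 adjusted over the list alone (adjusted p = 0.151 with an estimated correlation). Here too the cells that gave these transcripts cannot be told. Cholesterol synthesis and IL-17 and antimicrobial genes had medians of -0.52 and -0.55 (adjusted p = 0.152 and 0.417 with an estimated correlation). Without the first cKO HDM library the IL-17 and antimicrobial median was 0.22.

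Markers of other cell types were lower in the same comparison. The 15 endothelial genes had a median of -2.39, all negative, with Calcrl and Cdh5 past the threshold and 11 adjusted over the list alone (adjusted p = 0.021 with an estimated correlation). The collagens Col3a1 (-3.19 ± 0.43), Col1a1 (-3.55 ± 0.52) and Col1a2 (-4.63 ± 0.90) were the 3 of 10 fibroblast and smooth muscle genes that fell, with 8 adjusted over the list alone (adjusted p = 0.021 with an estimated correlation). Bgn fell by 4.95 ± 0.87, and Acvrl1, an endothelial receptor, by 3.56 ± 0.52. The haemoglobin genes Hba-a1 and Hba-a2, near-identical copies, fell, at -5.69 ± 1.00 and -5.67 ± 1.00. Of 5 macrophage and dendritic cell genes Lyz2, lysozyme, which type 2 cells also express, fell by 1.96 ± 0.32, with 2 adjusted over the list alone (adjusted p = 0.105 with an estimated correlation). The endothelial share of reads was 0.0763% (95% interval 0.0689 to 0.0843) and 0.0823% (0.0742 to 0.0911) in cKO HDM, close to that in PBS. Clca1 at 0.65 ± 0.46, Muc5ac at 0.25 ± 0.96, Socs3 at 0.01 ± 0.95, Scgb1a1 at -0.06 ± 0.24 and Epcam at -0.23 ± 0.31 did not pass, and Il33 at -2.91 ± 0.66 missed the threshold (limma adjusted p = 0.0697). Without the second WT HDM library 3 genes passed, without the first and second cKO HDM library 13 and 12, and without the second WT PBS library 24. Without the first and second cKO PBS library 115 and 117 passed.

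**Figure D3:**
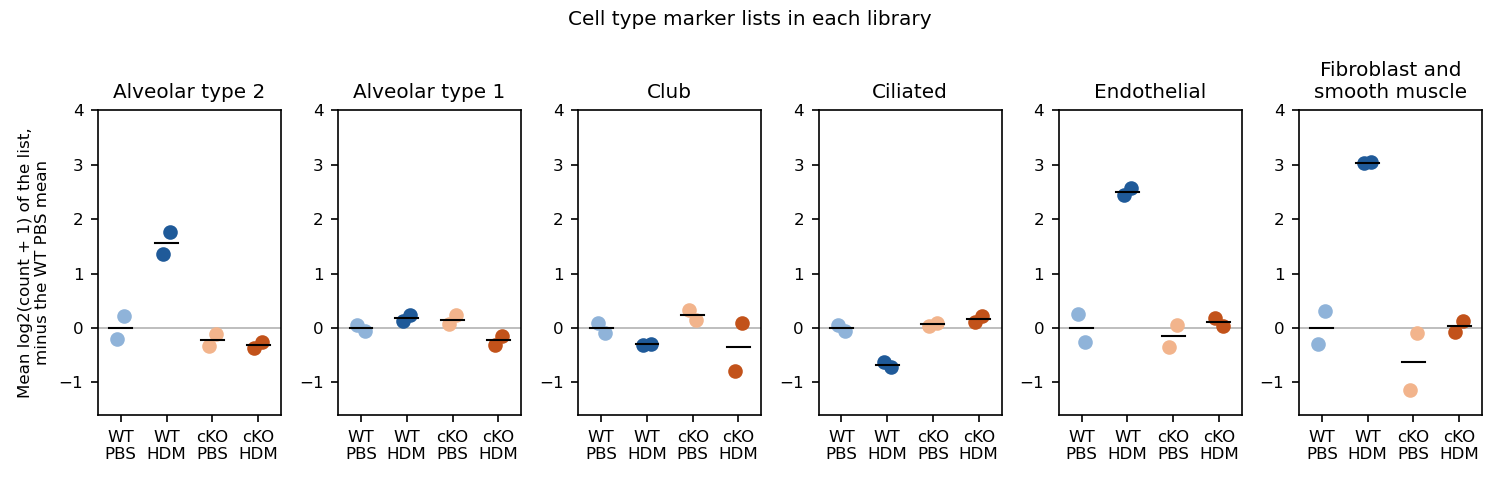
Mean log2(count + 1) of 6 cell type lists in each library, minus the WT PBS mean (vertical axis), by group (horizontal axis), with points for the 2 libraries and a bar for their mean. Both WT HDM libraries stand above the others for the alveolar type 2, endothelial, and fibroblast and smooth muscle lists.

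Genotypes were also compared without allergen. The largest fall by unadjusted p was Timp2 at -2.66 ± 0.47 log2 units (limma adjusted p = 0.287), which did not pass. Cxcl12, a stromal chemokine, had 0 reads in both cKO PBS libraries, at least 5.03-fold lower against a floor of 3 reads per library, and did not pass. Clca1 stood at 1.61 ± 0.46 and Kcnj15 at 1.19 ± 0.34 (limma adjusted p = 0.659 for both). No gene passed with limma, edgeR or DESeq2, and 523 had an unadjusted p under 0.05 with limma and 410 with edgeR. No list passed, and the alveolar type 2 and endothelial medians were -0.01 and 0.12. Scgb1a1 stood at 0.74 ± 0.24, Sftpc at 0.13 ± 0.28 and Il33 at -0.59 ± 0.66. The cKO PBS libraries were the shallowest, and without the first or the second of them 53 and 315 genes passed.

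The interaction asked whether the response to HDM differed between genotypes. The response of Scd1, cKO minus WT, differed by -2.71 ± 0.35 log2 units (limma adjusted p = 0.00828), and that of Hc by -2.77 ± 0.43 (limma adjusted p = 0.0386). Scd1 lies on chromosome 19 (44394450 to 44407709) and Hc on chromosome 2 (34983329 to 35068506), both protein-coding, in mm10. These 2 genes passed and both were lower, and edgeR called 7, all lower. Cxcl15 at -1.90 ± 0.34 (limma adjusted p = 0.122), Fasn at -1.95 ± 0.37 and Col3a1 at -3.21 ± 0.61 (limma adjusted p = 0.14 for both) did not pass. The 23 alveolar type 2 genes had a median of -1.58, with 2 past the threshold and 20 adjusted over the list alone (camera adjusted p = 8.2e-14, but adjusted p = 0.121 with an estimated correlation). Endothelial genes moved with them, with a median of -2.12, 0 past the threshold and 8 adjusted over the list alone (adjusted p = 0.0515 with an estimated correlation). Of 24 lists 9 passed at the preset correlation and 0 with an estimated one. Il33 stood at -2.32 ± 0.93 and Stat3 at -1.18 ± 0.55 (limma adjusted p = 0.638). Both calls were lost in 5 of the 8 fits that left out a library, and without the first and second cKO PBS library 19 and 115 genes passed.

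Averaged over genotypes, HDM raised Chil4 by 6.02 ± 0.61, Chia1 by 3.27 ± 0.31, Retnla by 2.72 ± 0.29 and Clca1 by 2.75 ± 0.32 log2 units (n = 4 against 4). Vim, vimentin, rose by 3.83 ± 0.53, and H2-K1 and H2-D1 rose by 1.25 ± 0.20 and 1.22 ± 0.17. Cyp2f2 fell by 0.88 ± 0.15 and Selenbp1 by 1.02 ± 0.17. In all 27 genes rose and 3 fell (limma), and edgeR called 39 and 4. Of the 18 IL-13 and mucous genes 6 rose, and 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 5.2e-10, and adjusted p = 0.0363 with an estimated correlation). Endothelial genes had a median of 1.16 with 0 past the threshold and 9 adjusted over the list alone (adjusted p = 0.0363 with an estimated correlation). Their median was 2.42 in WT and 0.19 in cKO, so this average does not show a rise in each genotype. Without the second WT HDM library 10 genes passed, without the first cKO HDM library 18, and without the first and second WT PBS library 13 and 15. Without the first and second cKO PBS library 71 and 193 passed.

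Averaged over treatments, Scd1 fell by 2.11 ± 0.17 log2 units in the libraries labelled cKO, Lpcat1, a surfactant lipid enzyme, by 1.72 ± 0.26, Slc34a2 by 1.32 ± 0.20 and Fasn by 1.19 ± 0.19 (n = 4 against 4). Of 9 genes that passed, all lower, 6 were alveolar type 2 genes, with 18 of 23 adjusted over the list alone (camera adjusted p = 8.9e-12, but adjusted p = 0.156 with an estimated correlation). Col1a1 fell by 2.41 ± 0.37, and endothelial genes had a median of -1.04 with 0 past the threshold and 8 adjusted over the list alone (adjusted p = 0.0404 with an estimated correlation). EdgeR called 1 higher and 20 lower. Only 4 of the 9 genes had no overlap between the libraries of the genotypes. Under HDM alone Scd1 stood at -3.46, and its response to HDM differed between genotypes by the interaction test. No gene passed under PBS, so these averages do not show a difference in each treatment. With an additive model of genotype and treatment 0 genes passed with limma, where 632 had an unadjusted p under 0.05 in the model with 1 mean per group. Leaving out 1 library of WT HDM, cKO HDM or WT PBS gave 1 to 4 genes, and leaving out the first or second of cKO PBS gave 38 and 181.

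The genes that rose with HDM in WT and those lower in cKO under HDM shared 17 members. Lists drawn independently would share 0.197, a value that leaves out the WT HDM libraries common to both comparisons. Simulated groups without effects shared 0, but these made a mean of only 0.04 and 0.02 calls, so that count gives no scale for the observed 17. Part of the overlap may come from the common libraries. Across genes the fold changes of these comparisons correlated at r = -0.73, with -0.51 in the simulation. Their covariance was -0.68, with -0.28 in the simulation. The simulation gave a gene the same dispersion in every group. The real replicates correlated at 0.68 in WT HDM and 0.77 in cKO HDM and WT PBS. The gaps to the simulation are therefore no measure of a real effect. Both WT HDM libraries stood above the others for the alveolar type 2 and endothelial lists, so using 1 in each comparison does not remove what they share. With 1 WT HDM library in each comparison, so that none was common, the covariance was -0.33 and the correlation -0.27 both ways round, where simulated comparisons without a common library or any group effect correlated at 0.0025 on average. Of 3 and 14 calls 3 were shared one way and of 18 and 3 calls 2 the other, with 0.00559 and 0.00719 for lists drawn independently.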

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

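The tests of explanations in this part were chosen for patterns already seen. For other cell types and for reads outside the deleted exons, the expected outcomes were also written after the results had been seen. Those of the other tests were written before each was run. Results are listed here because the response to HDM differed between genotypes by the interaction test. The difference, cKO minus WT, was -2.71 log2 units for Scd1 and -2.77 for Hc. Of the lists that passed, the medians were -1.58 for alveolar type 2, -0.52 for alveolar type 1, -2.12 for endothelial, -2.51 for fibroblast and smooth muscle, -1.96 for macrophage and dendritic cell, -3.66 for MHC class II, -0.67 for STAT3 target and -0.27 for ribosomal protein genes. The ciliated list had a median of 0.83. None of these list calls held with an estimated correlation.

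Endothelial, fibroblast, macrophage, B cell, granulocyte and erythroid lists took a higher share of reads in both WT HDM libraries than in any of the other 6. That of T and NK cells did so in the second WT HDM library alone. The granulocyte share was 0.0128% (95% interval 0.0101 to 0.0160) in the first WT HDM library. This interval overlaps that of the first cKO PBS library, at 0.0103% (0.0066 to 0.0154). The macrophage list holds Lyz2, which is also in the alveolar type 2 list. The values argue against unequal depth as the source of the endothelial difference. After every library was thinned to 232556 reads, the endothelial median of cKO against WT under HDM was still -2.28. Cells or RNA of other types are a candidate source. In WT HDM 96% of the 25 measured endothelial and fibroblast or smooth muscle genes were higher than in WT PBS, but the same genes prompted the explanation, so this adds no support for it. The sort for airway epithelial cells would be meant to remove such cells. Whether the sort let more of them through or HDM changed the tissue of WT mice stays open, because both coincide with the group.

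Alveolar type 2 transcripts were lower in the libraries labelled cKO than in WT under HDM (camera adjusted p = 0.0637 with an estimated correlation). A single WT HDM library does not account for it, since without either in turn the list median stayed at -1.59 or below. A lower share of type 2 cells with the other epithelial types in proportion is argued against only weakly. Club and ciliated genes moved apart by -0.89 ± 0.30 (SE), and by -0.49 ± 0.14 without the first cKO HDM library and -1.28 ± 0.14 without the second. With the spread of all 8 libraries the SE of either would be 0.36, and -0.49 would lie within 2 SE of 0. A change in the mix of several cell types and a difference set by genotype, which the design names, may each remain, and the same 2 libraries carry the endothelial transcripts.

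Stat3 was not lower in the PBS libraries labelled cKO. The 95% interval of its difference ended at -0.43 and so excluded the estimate of -0.78 found under HDM, which argues against imprecision of the PBS comparison alone. That reading is weak, because the HDM estimate has a standard error of 0.39 of its own and the interaction had an unadjusted p of 0.0488 with limma (adjusted p = 0.638). The PBS difference also depends on single libraries, at -0.031 without the second WT PBS library and 0.84 without the first. Reads from exons outside the deleted part, or from cells without the deletion, cannot be told apart from an intact gene here, since gene totals, with a difference of 0.41, hold no reads per exon. A mislabelled sample was not tested.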

How the results depend on the processing

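Of the alternatives listed with the methods, only the edgeR and DESeq2 fits were chosen after seeing the data. Of 83 named results that passed, all 83 passed in the same direction with a pseudocount of 5, quantile normalization, library weights, edgeR or DESeq2, 82 with recomputed size factors, 78 with robust settings, 43 with a pseudocount of 0.2, 33 without a filter and 4 without a variance trend. Without the first and second library of a group 38 and 15 passed (WT HDM), 35 and 37 (cKO HDM), 40 and 44 (WT PBS), and 83 and 83 (cKO PBS). None of the 83 changed direction in these fits. Counts of genes are given in the order HDM in WT (39), HDM in cKO (4), genotype under HDM (43), interaction (2), HDM averaged (30) and genotype averaged (9), where they moved by over 1.5 times. A pseudocount of 5 gave 108, 14, 99, 12, 60 and 31. A pseudocount of 0.2 gave 16 for HDM in WT, 0 for HDM in cKO, 0 for the interaction and 1 for genotype averaged. No filter gave 14, 0, 9, 0, 13 and 1, and a minimum mean of 50 gave 77, 16, 85, 9, 59 and 37. Quantile normalization gave 101, 12, 96, 9, 51 and 25, and no trend 1, 1, 0, 0, 8 and 0. Library weights gave 118 for HDM in WT, 107 for genotype under HDM and 21 for genotype averaged, and robust settings 16 for the last. Fits of only the groups compared gave 190, 0 and 142, and the additive model 0 for genotype averaged. EdgeR gave 59 for HDM in WT, 7 for the interaction and 21 for genotype averaged, and DESeq2 134, 28, 130, 27, 106 and 67. The cause was not tested.

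Leaving out 1 library gave 3 to 110, 0 to 320, 3 to 117, 0 to 115, 10 to 193 and 1 to 181 genes, and 0 to 315 for genotype under PBS (0). The lone library of a group is then assumed to vary like the others. All the highest counts came without the second cKO PBS library, when that group rests on the shallowest one. HDM in WT and genotype under HDM do not use the cKO PBS mean, so their fold changes are unaffected by that omission. Their counts can then change only through the spread shared by the groups, to which cKO PBS no longer adds. The cKO PBS replicates correlated least, at r = 0.56. Lists that passed numbered 11 to 13 for HDM in WT (12), 1 to 5 for HDM in cKO (4), 9 to 13 for genotype under HDM (10), 0 to 2 under PBS (0) and 7 to 13 for the interaction (9). No filter gave 19, 16 and 16 lists for HDM in WT, genotype under HDM and the interaction. An estimated correlation gave 4, 0, 3 and 0 lists (HDM in WT, HDM in cKO, genotype under HDM, interaction), and fry 0 for HDM in cKO and 5 for the interaction.

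Values that did not pass changed sign as follows. Stat3 (cKO against WT) under PBS ranged from -0.031, without the second WT PBS library, to 0.84, and under HDM from -0.91 to -0.65 with no change of sign. With 1 library left out the ranges were -0.43 to 0.10 for Epcam and -0.44 to 0.22 for Scgb1a1 (HDM in WT), and -0.19 to 0.56 for Stat3 (HDM in cKO). Under HDM, cKO against WT, they were -0.58 to 1.08 for Muc5ac, -0.040 to 0.060 for Socs3, -0.39 to 0.27 for Scgb1a1 and, as a median, -1.66 to 0.22 for the IL-17 list, which passed in the full set. Under PBS they were -1.20 to 0.018 for Il33 and -0.24 to 0.51 for Sftpc. Quantile normalization gave 0.28 for Scgb1a1 under HDM, and -0.055 for Sftpc and 0 for Scgb1a1 under PBS.

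The replicate numbers did not pair the samples, with correlations of deviations from -0.016 to 0.018, and with the replicate block 80 of the 83 results passed. The block gave 43, 5, 48, 3, 34 and 12 genes and moved no count by over 1.5 times. At 232556 reads per library 31, 3, 38, 1, 28 and 13 genes passed, and with limma 4% of simulated 2-fold changes were found at the real depth, so small changes were largely out of reach.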

Other observations

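The clock score, the fatty acid, circadian, fasting and glucocorticoid lists and the count of sex-linked reads were chosen after the results had been seen. The expected outcomes of the fatty acid, circadian and fasting tests and of the splits were written before each was run. Genes of the circadian clock were examined between genotypes under HDM because Tef had passed. None of the 16 measured members of the added list passed over all genes tested. Dbp stood at 4.25 ± 1.24 log2 units, Per2 at 2.47 ± 0.70 and Nr1d2 at 2.39 ± 0.65, while Npas2 stood at -3.13 ± 0.79 and Arntl, their activator, at -2.18 ± 0.88 (cKO against WT, n = 2 each). Of the 16, 5 passed adjusted over the list alone, and the mixed test of fry gave an unadjusted p of 9.5e-04 (fry adjusted p = 0.0019 over the 4 added lists). That test does not compare the list with other genes. It also passed in 5 of the other 6 comparisons, with adjusted p = 0.0319 for HDM in WT, 0.0059 for HDM in cKO, 0.0116 for cKO against WT in PBS, 0.0064 for the interaction and 0.0045 for genotype averaged, but takes no account of direction. Camera compares with other genes in 1 direction and gave adjusted p = 0.224 (adjusted p = 0.262 with an estimated correlation). The list holds genes of opposite phase, so that result decides nothing.

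A score of 8 clock output genes minus 5 genes of the opposite phase, without Tef, was -0.81 and -1.64 in WT HDM and 2.72 and 1.92 in cKO HDM. It was -0.10 and 0.55 in WT PBS and 0.67 and -0.32 in cKO PBS. Under HDM the score of cKO against WT differed by 3.54 ± 0.59 (SE), with 12 of the 13 genes on the side their phase assigns, and under PBS by -0.047 ± 0.59. WT HDM lay below the other 6 libraries by 0.48, and cKO HDM lay above all others. HDM against PBS was 2.14 ± 0.59 in cKO and -1.44 ± 0.59 in WT, where the 95% interval of -3.07 to 0.18 includes 0. A difference in the hour of collection may be behind this, and an effect of HDM or genotype on the clock stays open, since no collection times are given in the sources used here. These genes were examined because they stood out, and the score is a hypothesis from the same data.

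Scd1, Fasn and Scd2 (the last chosen after its values were seen) fell together in the libraries labelled cKO under HDM. Of 14 other genes of fatty acid synthesis, 11 were lower, with a median of -0.81, 0 past the threshold over all genes and 3 adjusted over the list alone (camera, unadjusted p of 0.0033, adjusted p = 0.0132 over the 4 added lists, but adjusted p = 0.179 with an estimated correlation). Acly stood at -1.09 ± 0.31 and Elovl1 at -1.52 ± 0.44. Alveolar type 2 cells make surfactant lipid, so these values are consistent with a lower contribution of those cells as well as with lower synthesis per cell.

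A fasting or PPAR alpha response was also tested between genotypes under HDM. The 14 measured genes of the added list had a positive median of 0.37 but did not pass (camera, unadjusted p of 0.128, adjusted p = 0.218). The glucocorticoid list, added alongside, had a median of -0.38 and did not pass with camera (adjusted p = 0.218). By the mixed test of fry, used for the clock genes above, the fatty acid and glucocorticoid lists also passed (adjusted p = 3.8e-04 and 0.0104) and the fasting list did not (adjusted p = 0.44). The fry test in 1 direction gave adjusted p = 0.0162 for each of the fasting list, with 10 of 14 genes higher, the fatty acid and the glucocorticoid list, and 0.107 for the circadian list. Like the mixed test it makes no comparison with other genes. The bound set beforehand was a missed threshold, which does not show that the genes did not differ, so the question stays open.

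Reads of Xist, expressed in females, and of Y-linked genes both reached 3 in 8 of 8 libraries, with 11 to 44 reads of Xist and 3 to 56 of 4 Y-linked genes. Each library may hold RNA of both sexes, through pooling or carry-over between libraries.

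Other splits of the 8 libraries into 4 and 4 were fitted as 2 groups. For HDM against PBS, 1 of the 35 splits gave as many genes, the real one with 11, and the highest of the others gave 0. Most of the other splits divide the libraries of a group, which may not be independent, so this count cannot exclude chance. It also does not cover the 30 genes of the model with 1 mean per group. For cKO against WT the real split gave 0 genes in this simpler fit and the highest other, the split by treatment, gave 11. All 35 splits must then give as many, so the count says nothing about the 9 genes of the model with 1 mean per group.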
